A study of Escherichia coli with 3 samples.

How the data were processed

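RNA from 2 kinds of Escherichia coli culture was compared on 3 two-colour microarray slides. Both cultures were of the strain WAM132 melR, per the labels; the labels do not say more on its chromosomal melR gene. One carried a plasmid that encodes MelR*, a mutant form of the melibiose regulator MelR, and the other carried a plasmid without melR. Cells were grown to an optical density of 0.5 in minimal medium with fructose and amino acids and without melibiose. Each slide was hybridised with both RNAs, so the ratio of its channels is the comparison, and the 3 slides are the replicates. The labels do not say whether the slides came from separate cultures or whether dyes were swapped. The p-values of single genes therefore measure the spread between these slides, which may be technical. A dye effect shared by the slides would not cancel.

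The authors deposited log2 ratios of the channels, 1 value per spot and slide, and scanner intensities were not used here. The image analysis, background correction, dye normalization and filters behind these values are not given in the sources used here. On all slides at least 99.97% of the deposited log2 values were the log2 of a ratio that was a whole number of thousandths, within 0.01 thousandths. The ratios were therefore rounded to 3 decimals before the logarithm was taken. The medians over all spots were -0.38 on slide 1, 0.05 on slide 2 and -0.50 on slide 3, so the deposited values were not centred on 0. Which channel is the numerator is not stated. The labels give MelR* RNA for channel 1 and RNA without MelR for channel 2, and the melR gene, which of both plasmids only the MelR* plasmid carries, had a positive value on each slide. Positive values were therefore read as likely higher in MelR* cells, and signs were kept as deposited. The correlations across genes were positive for all 3 pairs of slides.

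Each slide held 14400 spots. A GEO annotation table of the array gave 1 gene symbol to 9012 spots, several to 0 spots and none to 5388 spots, which are unnamed here. The named spots covered 4173 gene IDs with 4148 symbols. Symbols were updated through the gene ID with a table of the MG1655 assembly ASM584v2, which lacked 42 of the IDs. These kept the array's symbol and entered no gene list. Most genes, 4121, had 2 spots, and 11 genes had 26. No genome coordinates are given, since the genome build behind the array design is not stated.

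Spots of a gene were averaged per slide on the log2 scale, and 4011 genes with a value on all 3 slides were tested. The other 162 genes lacked a slide. Each slide was then centred on the median of its genes. The centring subtracted -0.34 on slide 1, 0.14 on slide 2 and -0.47 on slide 3. The mean log2 ratio was tested against 0 (two-sided) with limma 3.58.1 in R 4.3.3 (intercept-only fit, eBayes, Benjamini-Hochberg adjustment). A gene passed at an adjusted p under 0.05. Intervals are 95% intervals from the moderated standard error, and folds are on the ratio scale as deposited. Gene lists were tested with camera (limma) at the preset inter-gene correlation of 0.01, over the 26 of 27 lists with at least 3 measured genes. Camera with an estimated correlation and fry were run beside it. At the preset correlation camera compares the genes of a list with all other genes and treats genes as nearly independent. Its p-values therefore do not measure the spread between slides alone, and can be far smaller than 3 slides would allow.

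The design, the alternatives, the 27 gene lists and the rule for named genes were fixed before the data were examined. The rule names melA, melB and melR. It then names the 12 genes with the largest positive and the 12 with the largest negative means among those that passed. Where fewer than 12 passed, places were filled by genes with the same sign on all 3 slides and the smallest p. Of each list described, up to 3 members with the smallest p are named. The alternatives fixed with the design were no centring, scale and quantile normalization between slides, genes with 2 slides, medians of spots, spots tested alone, a trended and robust eBayes, an unmoderated test, 2-fold thresholds, a turned sign of 1 slide, and each slide left out. Leaving out spots with simple ratios and centring runs of 300 spot numbers were added after the data were seen.

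Only 3 slides limit the precision. Tested on simulated data with the variance of the real fit, 4011 genes and 200 changed genes, limma recovered 16.8% of changes of 1 on the log2 scale, 85.3% of changes of 2, 95.1% of changes of 3 and 99.7% of changes of 5. Where only 3 genes changed by 5, it recovered 87.7%. In a simulated shift of 0.5 of the 54 ribosomal protein genes, camera gave an adjusted p of 2.84e-19 with the preset correlation and 0.192 with an estimated one. The second setting thus missed a shift of that size with 3 slides after adjustment, in a single draw. Its unadjusted camera p there was 0.00738. The simulated genes were drawn independently, which favours the preset correlation, so the simulation cannot show how either setting treats correlated genes. In the real data the estimated correlations ran from -0.15 (genes next to the mel locus) to 0.80 (melibiose genes). They were 0.29 for ribosomal proteins and 0.65 for ATP synthase and aerobic respiration. The unadjusted camera p with these correlations was 0.0861 and 0.141. Several lists share the same adjusted p with an estimated correlation, because the adjustment ties them although their unadjusted p differ.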

Results

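Gene expression was compared between Escherichia coli cells that carried MelR* and cells without MelR, both grown on fructose with no melibiose. MelR is the activator of melAB, the operon for melibiose uptake and cleavage, so the comparison asks which genes respond to the mutant regulator without its sugar. The data are 3 two-colour slides, each a direct hybridisation of both RNAs. Values were present for 13572, 14172 and 14222 of the 14400 spots on slides 1, 2 and 3. Neighbouring spots of the same gene correlated at r = 0.74, 0.80 and 0.77 on the 3 slides, over 4314 pairs. The dnaK gene was printed at many places, and its spots had an SD of 0.47 on slides 1 and 2 (314 spots each) and 0.19 on slide 3 (313 spots). Across the 4011 tested genes the slides correlated more weakly. Pearson's r was 0.34 for slides 1 and 2, 0.29 for slides 1 and 3 and 0.24 for slides 2 and 3, and Spearman's rho was 0.36, 0.37 and 0.24. Genes are not independent replicates, so no p-value is attached to these correlations. Positive log2 ratios are read as likely higher in MelR* cells, because channel 1 held MelR* RNA and melR itself was positive on each slide.

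The melibiose genes had by far the highest ratios. The melR gene (b4118), which encodes the regulator and is the gene that differs between the plasmids, had a mean log2 ratio of 5.87 ± 1.10 (SD, n = 3), a fold of 58.4 with a 95% interval of 26.7 to 128.0. The melA gene (b4119), for the alpha-galactosidase that cleaves melibiose, had a mean of 5.57 ± 0.85 (SD, n = 3), a fold of 47.6 with an interval of 25.2 to 89.6. The melB gene (b4120), for the melibiose permease, had a mean of 3.39 ± 2.54 (SD, n = 3), a fold of 10.5 with an interval of 1.93 to 57.3. Its values were 4.66 and 5.05 on slides 1 and 2 but 0.47 on slide 3, where both of its spots were listed at a ratio of exactly 1. Over slides 1 and 2 alone melB had a fold of 29.0. Only melA and melR of the 4011 genes had a mean ratio of at least 16-fold in either direction.

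With limma's moderated test the adjusted p over all genes was 0.0829 for melA, 0.0905 for melR and 0.374 for melB, so none of them passed 0.05. Adjusted over the list alone, all 3 passed, with adjusted p of 6.20e-05 for melA, 6.77e-05 for melR and 0.0162 for melB. The list passed camera with an adjusted p of 9.21e-06 (adjusted p = 0.494 with an estimated correlation). These list results include melR, which of both plasmids only the MelR* plasmid carries. Only melA and melB therefore inform on a response to MelR*. The call for melA over all genes depended on single slides: without slide 1 its limma adjusted p was 0.026, and without slide 2 it was 0.56. Without centring melA and melR passed, with an adjusted p of 0.00475 and 0.00719. Over the alternatives with a limma p for these genes, the adjusted p of both ran from 0.00109 to 0.56. The unmoderated test and the turned signs gave only counts of genes.

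The genes next to the mel locus did not share these ratios. Of the 6 measured neighbours (adiA, adiY, yjdF, dcuB, dcuR and dcuS), 3 had positive and 3 negative means, and the list median was -0.076. The members with the smallest p were dcuB at -0.51 ± 0.41, dcuR at -0.52 ± 0.94 and adiA at 0.16 ± 0.17 (SD, n = 3), and the list did not pass camera (adjusted p = 0.646). The dcuR value rests on slide 2, and without that slide it was 0.018.

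Of all 4011 genes, the mel genes included, 0 passed limma's test at an adjusted p of 0.05, while 525 had an unadjusted p under 0.05, against 200.55 expected by chance. The unmoderated one-sample test also called 0. Of the 525 genes, 299 were positive and 226 negative. Without centring the split was 46 positive and 465 negative, because that setting moved the median of all genes by -0.22 on the log2 scale. The sign was the same on all 3 slides for 42.9% of genes, where independent signs give 25%. Only 4 genes were at least 2-fold from the slide median in the same direction on all 3 slides: melA, melR and glpB above it and rhaM below it.

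The 10 other positive genes with the smallest p had folds from 1.85 to 2.56, and none passed (adjusted p = 0.374 for each). First was glpB, a subunit of the anaerobic glycerol-3-phosphate dehydrogenase, at 1.36 ± 0.0084 (SD, n = 3). The gene hslV, for the protease subunit of HslVU, was at 1.03 ± 0.11 and oppA, the periplasmic oligopeptide-binding protein, at 1.09 ± 0.29. Respiratory genes filled most of the other places. ATP synthase subunit gene atpH was at 1.09 ± 0.21, NADH dehydrogenase gene nuoA at 1.06 ± 0.22 and succinate dehydrogenase gene sdhC at 0.96 ± 0.17. The cytochrome bo oxidase genes cyoA and cyoC were at 1.09 ± 0.33 and 0.91 ± 0.16. The list was completed by prs, for phosphoribosyl pyrophosphate synthetase, at 0.89 ± 0.13 and by the IS5 transposase gene insH1 at 0.91 ± 0.18. Since IS5 has near-identical copies, the insH1 probe may not separate them.

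The 12 negative genes with the smallest p had means from -1.59 to -0.72, and none passed (adjusted p = 0.374 for each). The lowest was rhaM, a rhamnose mutarotase, at -1.59 ± 0.48 (SD, n = 3). The fucose mutarotase gene fucU was at -0.84 ± 0.19, the colanic acid gene wcaB at -0.80 ± 0.14 and gss, for glutathionylspermidine synthetase, at -0.95 ± 0.35. The genes dctR at -1.15 ± 0.24, yjbB at -1.01 ± 0.20, yibG at -1.09 ± 0.40 and ydjM at -0.95 ± 0.35 also stood below the slide median, as did ymgC at a ratio of 0.499. So did trmO at -0.77 ± 0.12, yeeJ at -0.72 ± 0.073 and ydiP at -1.12 ± 0.57.

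**Figure D1:**
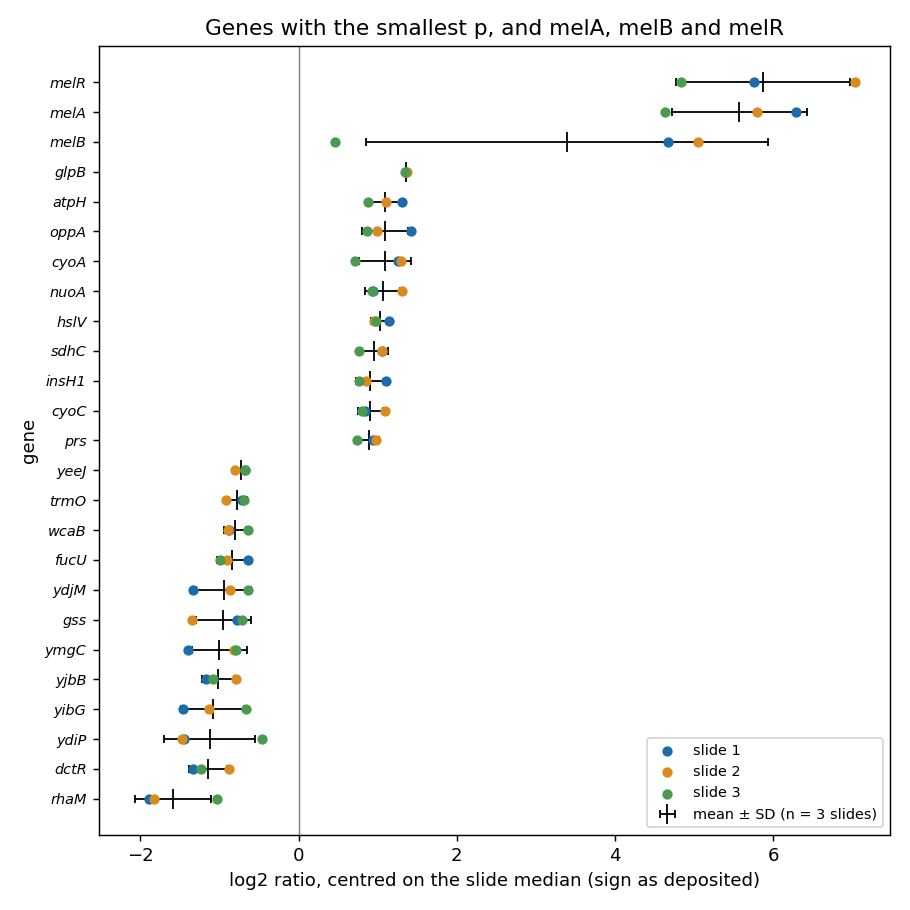
Log2 ratio (horizontal axis, centred on the slide median) of each named gene (vertical axis); coloured points are the 3 slides, and black bars give mean ± SD (n = 3). The melR and melA points lie above 4 on every slide, melB on slide 3 lies at 0.47, and the means of the remaining genes lie between -1.59 and 1.36.

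The lists of ATP synthase and aerobic respiration, ribosomal proteins and the TCA cycle passed camera in the positive direction. All 29 genes of ATP synthase and aerobic respiration had positive means, 28 of them on all 3 slides, with a list median of 0.91. The smallest p belonged to atpH, nuoA and cyoA, given above. All 54 ribosomal protein genes had positive means, 50 of them on all 3 slides, with a median of 0.67. Examples were rplC at 0.97 ± 0.28, rplD at 1.01 ± 0.32 and rpmH at 0.93 ± 0.36 (SD, n = 3). In the TCA cycle and glyoxylate shunt 16 of 18 genes were positive, with a median of 0.62 (0.40 without centring), led by sdhC, sdhD at 0.86 ± 0.29 and sucA at 0.97 ± 0.46. Camera's adjusted p was 9.96e-19, 3.90e-23 and 9.21e-06 for the 3 lists (adjusted p = 0.494 for each with an estimated correlation). No member passed over all genes. Adjusted over the list alone, 23 respiratory, 17 ribosomal and 4 TCA cycle genes passed.

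Of the 4 lists of sugar genes, 2 passed camera. All 11 genes of the PTS and fructose uptake list had positive means, with a median of 0.59 (0.37 without centring). Most of their products take part in bringing in the carbon source of the medium and other sugars, while cra encodes a regulator. The list had a camera adjusted p of 8.04e-05 (adjusted p = 0.494 with an estimated correlation). The fructose genes fruB and fruA were at 0.79 ± 0.26 and 0.61 ± 0.17, and ptsH at 0.67 ± 0.28 (SD, n = 3). Among operons for maltose, galactose, ribose and other sugars under CRP, the cyclic AMP receptor protein, 26 of 39 genes were positive, with a median of 0.24 (0.014 without centring and 0.14 with runs of 300 spots centred) and an adjusted p of 0.00738 (adjusted p = 0.494 with an estimated correlation). The periplasmic binding proteins malE and rbsB were at 1.02 ± 0.34 and 1.15 ± 0.50, and gatY at 0.75 ± 0.15. In both lists 0 genes passed over all genes and 0 adjusted over the list alone. The arabinose, rhamnose and xylose operons, whose regulators belong to the same AraC family as MelR, had 10 positive and 8 negative genes. Their median was 0.029 and their mean -0.21, and the list did not pass (adjusted p = 0.577). The members with the smallest p were rhaB at -0.88 ± 0.56, rhaS at -0.57 ± 0.20 and rhaA at -0.88 ± 0.70. Of the other rhamnose genes in the list, rhaD was at -0.80 ± 0.77, rhaR at 0.20 ± 0.61 and rhaT at 0.27 ± 0.14. The rhamnose mutarotase gene rhaM, at -1.59, was not in the list. The pooled median therefore does not describe the rhamnose genes alone. Of the lactose operon only lacZ (0.25 ± 0.69) and lacI (-0.47 ± 2.24) had values on all slides, too few to test. The lacI value rests on slide 1, and without it was 0.72.

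The flagellar and heat shock lists passed camera in the positive direction, while 0 of their genes passed over all genes. Of 51 flagellar and chemotaxis genes 42 were positive, 27 of them on all slides, with a median of 0.41 (0.19 without centring and 0.24 with spots tested alone) and a camera adjusted p of 2.18e-07 (adjusted p = 0.494 with an estimated correlation). The flagellar genes flgI, fliH and flgC were at 0.73 ± 0.19, 0.88 ± 0.45 and 0.72 ± 0.27 (SD, n = 3). All 17 heat shock chaperone and protease genes were positive, with a median of 0.43 (0.21 without centring, and 0.83 with spots tested alone, where dnaK has 314 spots) and an adjusted p of 1.15e-06 (adjusted p = 0.494 with an estimated correlation). The heat shock genes were led by hslV, the chaperonin groS at 0.93 ± 0.27 and the chaperone dnaK at 0.82 ± 0.32. The estimated correlation of this list was 0.0011. Its unadjusted camera p with that correlation was 0.0306, the lowest of the lists tested. Adjusted over the list alone, 2 heat shock genes and 0 flagellar genes passed.

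The histidine, purine and pyrimidine, methionine and iron uptake lists also passed camera in the positive direction. Of the histidine genes 7 of 8 were positive (median 0.52, adjusted p = 0.0155, and adjusted p = 0.583 with an estimated correlation), with hisD at 0.85 ± 0.48, hisI at 0.57 ± 0.14 and the exception hisB at -0.75 ± 0.34. Of the purine and pyrimidine genes 15 of 22 were positive (median 0.27, adjusted p = 0.00976, and adjusted p = 0.494 with an estimated correlation), led by pyrC at 0.94 ± 0.34, purF at 0.80 ± 0.46 and purM at 0.58 ± 0.39. Of the methionine genes 10 of 12 were positive (median 0.22, adjusted p = 0.0359, and adjusted p = 0.494 with an estimated correlation), with metQ at 0.61 ± 0.36, metE at 0.79 ± 0.66 and metN at 0.56 ± 0.44. Of the iron uptake genes 24 of 40 were positive (median 0.13, adjusted p = 0.0168, and adjusted p = 0.616 with an estimated correlation), led by the enterobactin genes entC at 1.14 ± 0.49 and entB at 1.13 ± 0.67 and by exbD at 0.94 ± 0.54 (SD, n = 3). No member of these 4 lists passed over all genes, and 0 passed adjusted over the list alone. Without centring the medians were 0.30 for histidine, 0.049 for purines and pyrimidines, -0.0055 for methionine, which then did not pass (adjusted p = 0.0681), and -0.088 for iron uptake. Without slide 2 the adjusted p was 0.072 for purines and pyrimidines (median 0.13), 0.197 for methionine and 0.307 for iron uptake, and without slide 1 it was 0.145 for histidine (median 0.29); the iron uptake median was 0.29 without slide 1, 0.31 without slide 3 and 0.079 without simple-ratio spots. These adjusted p were the highest over the alternatives at the preset correlation, and the lowest were 0.0029, 0.0157, 0.000852 and 0.00396.

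General stress and acid resistance was the only list that passed in the negative direction. Of its 19 genes 17 had negative means, 9 of them on all slides, with a median of -0.40 (-0.62 without centring) and a camera adjusted p of 0.00498 (adjusted p = 0.612 with an estimated correlation). The catalase gene katE was at -0.52 ± 0.073, the trehalose gene otsA at -0.46 ± 0.17 and the acid chaperone gene hdeA at -0.68 ± 0.68 (SD, n = 3). Of its members 0 passed over all genes and 0 adjusted over the list alone. Without slide 2 the list's median was -0.14 and its adjusted p 0.313, which at the preset correlation was the highest over the alternatives, and the lowest was 3.64e-05.

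The remaining lists did not pass camera on the values of all 3 slides. Fimbriae, curli and colanic acid had 16 of 24 genes negative (median -0.20, or -0.42 without centring, adjusted p = 0.172), led by wcaB, csgD at -0.57 ± 0.39 and wcaD at -0.73 ± 0.67. That list passed with spots tested alone (adjusted p = 0.0307) and without slide 1 (0.045), and its adjusted p ran up to 0.379 over the alternatives at the preset correlation. Multidrug resistance and oxidative stress had 11 of 17 positive (median 0.29, adjusted p = 0.172), with sodA at 0.98 ± 0.48, but its median was 0.033 without slide 1, 0.18 without slide 3 and 0.068 without centring. Nitrogen assimilation had 9 of 16 positive (median 0.079, adjusted p = 0.247), with glnP at 0.80 ± 0.12, and envelope stress 9 of 14 (median 0.16, adjusted p = 0.247), with cpxA at 0.56 ± 0.29; without centring both medians were negative. With 1 slide left out the nitrogen median ran from -0.028 to 0.26 and the envelope stress median from 0.036 to 0.28, and with runs of 300 spots centred the latter was 0.25 (adjusted p = 0.0586, from which it ran up to 0.533 over the alternatives at the preset correlation). The medians were -0.037 for branched-chain amino acids (adjusted p = 0.577), -0.016 for tryptophan and aromatic amino acids (0.997), -0.079 for arginine (0.901) and -0.059 for cysteine and sulfur (0.901). They were -0.071 for anaerobic respiration and fermentation (0.901), -0.028 for the SOS response (0.901) and 0.035 for cold shock (0.775). The cysteine list had a camera direction opposite to that of its median, as did the arabinose, rhamnose and xylose list. In the lists that did not pass camera, 0 genes passed over all genes and 0 adjusted over the list alone. By fry, 0 of the 26 lists passed after adjustment and 7 had an unadjusted p under 0.05. The smallest fry p, 0.00448, belonged to fimbriae, curli and colanic acid, so fry and camera ranked the lists differently. The others were the heat shock, melibiose, TCA cycle, ribosomal, flagellar and respiratory lists, with fry p from 0.0130 to 0.0379.

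**Figure D2:**
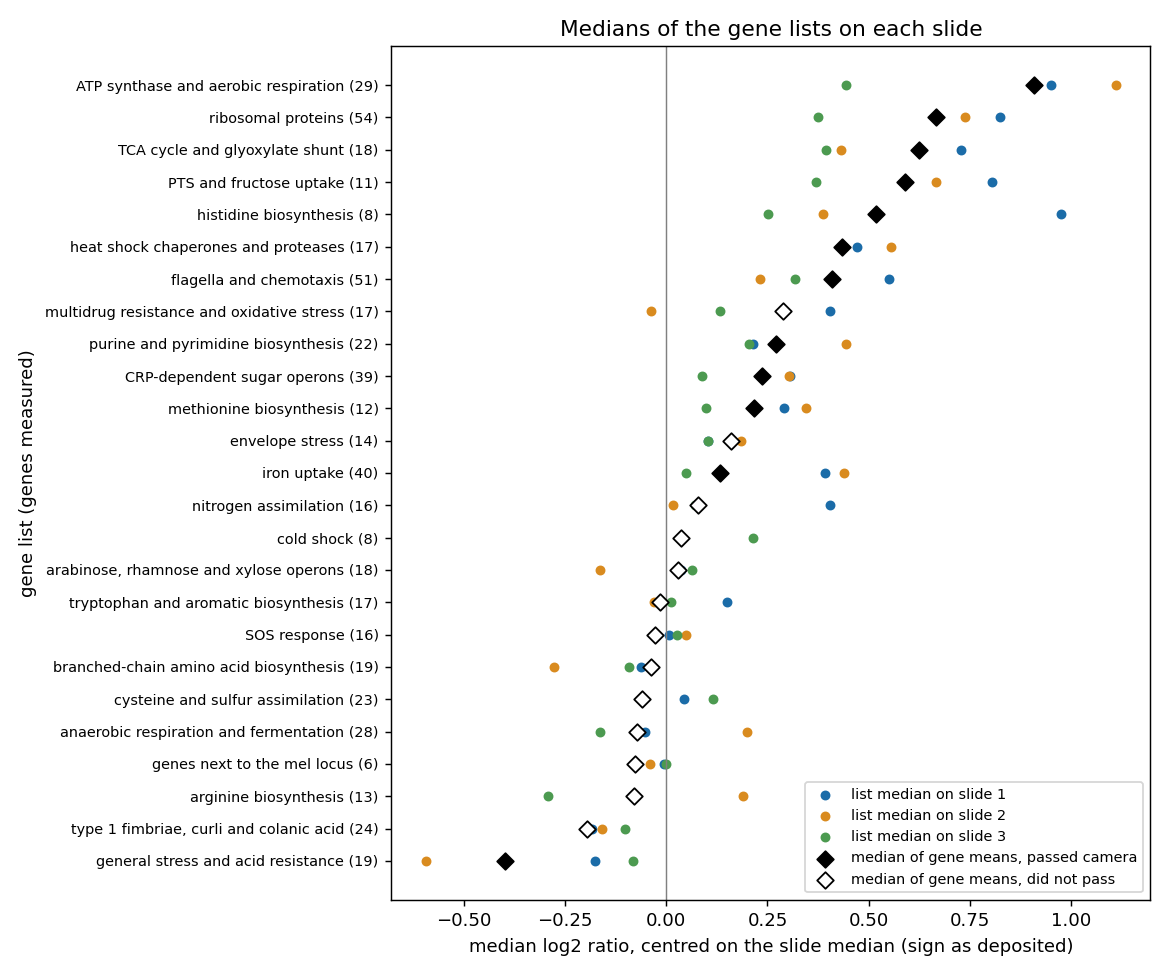
Median log2 ratio (horizontal axis, centred on the slide median) of each gene list (vertical axis, genes measured in brackets), without the mel list; coloured points are the list medians on each slide, and diamonds are medians of the gene means, filled where camera's adjusted p at the preset correlation was under 0.05. ATP synthase and aerobic respiration (0.91) and ribosomal proteins (0.67) have the highest medians, and general stress and acid resistance (-0.40) has the lowest.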

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

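The tests of repeat-spot scatter, of melB on slide 3 and of the places of unnamed spots were chosen after their results had been seen.

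Some unnamed spots had ratios that repeated across slides. Of 5388 unnamed spots, 147 were at least 2-fold from the slide median in the same direction on all 3 slides, 48 above and 99 below, against 9 named spots. Shuffling the spots within slides gave 4.80 on average and at most 12 in 100 draws. Of the 147 spots, 143 lay at places 4 to 15 of a run of 300 spot numbers in the first 23 runs. The 276 spots at these places form 69 groups of 4, whose means correlated between slides at r = 0.95, 0.96 and 0.94, and 60 groups had the same sign on all slides. What these spots hold is not given in the sources used here. They repeat at fixed places with fixed ratios, so printed ratio controls are not excluded, and no expression difference is read from them.

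Ribosomal protein and respiratory genes had positive ratios together, with medians of 0.67 and 0.91. Genes whose repeat spots scattered least, a stand-in for bright spots, were higher than those that scattered most, also outside the lists (0.11 against -0.30), a trend carried mostly by slide 1 (0.060 against -0.076 without it). The size of that trend falls short of both list medians. They lay above the middle 95% of 10000 random lists matched on scatter, by at least 0.48 (0.41 without slide 1). The random lists drew genes independently. Their band is therefore too narrow for these lists, whose estimated correlations were 0.29 (ribosomal) and 0.65 (respiratory), and it does not exclude the trend. A dye bias that grows with brightness would raise other abundant transcripts as much. For 10 such genes (such as ompC, acpP and hns) the median was 0.33, below the 0.53 to 0.76 of random draws of ribosomal genes. The gap was not shared by the slides. On slide 3 all of them but pal (0.050) and ompX (0.29) lay above the ribosomal median of 0.38. Low values of ompX (-1.63) and lpp (-1.22) came from slide 2. No intensities show how bright the 10 genes were, so this test cannot decide on a dye bias. Centring runs of 300 spots for slide position left the ribosomal median at 0.71. A dye bias may supply the shift or part of it, since those 10 genes had a positive median too. A difference in growth between the cultures also stays open and untested.

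The melB gene was listed at a ratio of 1 on slide 3. Loss of mel operon expression in that slide's RNA is argued against by melA, whose log2 ratio there was 4.63. A placeholder ratio in the file is a possible explanation that stays open. On slide 3, 4 neighbouring spot pairs, melB included, were both listed at 1, against 0.385 expected from single spots. That expectation takes neighbouring spots as independent, although those of the same gene correlated at r = 0.77 there. The first spots of the other pairs (eutT and unnamed) had deposited log2 ratios of at most 0.87 on slides 1 and 2. The first melB spot had 4.16 and 5.11. The excess of pairs therefore cannot decide, and the file gives no spot quality.

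The signs of the slides repeat each other more than turned signs do. The deposited signs gave 525 genes at an unadjusted p under 0.05, and the highest of the other sign patterns gave 90. Only 1 of the 4 patterns gave as many, the deposited one, but 4 patterns are too few for a share under 0.05.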

How the results depend on the processing

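The tests without simple-ratio spots and with runs of 300 spots centred were chosen after the data were seen. The mean log2 ratios of melA, melB and melR stayed positive under every alternative that gave a value. With the sign of 1 slide turned, only the count of genes was taken, so the mel means there are not covered. With 1 slide left out they ran from 5.22 to 6.04 for melA, 2.56 to 4.86 for melB and 5.29 to 6.39 for melR. No other alternative that gave a value went beyond these ranges. Over the alternatives with a limma p for these genes, the adjusted p ran from 0.00109 to 0.56 for melA and melR. It ran from 0.101 to 0.615 for melB. The unmoderated test and the turned signs are not in these ranges. The count of genes past the threshold was 2 without centring (melA 5.35, melR 5.65), 1 with scale normalization (melA 5.72), 2 with quantile normalization (melA 5.61, melR 5.83), 4 with the 2-fold rule on all slides and 1 without simple-ratio spots (melA 5.56), where melB gave no value. With 1 slide left out the count ran from 0 to 1, the 1 being melA without slide 1. It was 0 under the other settings, each turned sign included. Of the 26 lists 13 passed, and 12 to 14 did under other treatments of the values, 9 to 13 with 1 slide left out (9 without slide 2), 0 with an estimated correlation and 0 by fry. Genes with values on 2 slides were not run on lists, since camera needs all values. Some values changed sign, most of them near 0 and, with 1 slide left out, also dcuR and lacI, which were not. Without centring, which lowers all genes, adiA was at -0.062, and the list medians were -0.19 for arabinose, rhamnose and xylose, -0.19 for cold shock, -0.061 for envelope stress, -0.0055 for methionine, -0.14 for nitrogen and -0.088 for iron uptake. With spots tested alone the medians were -0.061 for arabinose, rhamnose and xylose and -0.033 for cold shock, and without simple-ratio spots the former was -0.015. With runs of 300 spots centred, adiA was at -0.057, cold shock at -0.028 and cysteine at 0.13. With 1 slide left out the values ran from -0.80 to 0.018 for dcuR and from -1.51 to 0.72 for lacI. The list medians then ran from -0.078 to 0.046 for arabinose, rhamnose and xylose, -0.058 to 0.013 for SOS, -0.19 to 0.0057 for anaerobic respiration, -0.24 to 0.068 for arginine, -0.073 to 0.048 for tryptophan, -0.029 to 0.083 for cysteine and -0.028 to 0.26 for nitrogen. The cause was not tested. The correlations between slides were 0.38, 0.33 and 0.26 over genes with a mean absolute ratio above the median. No paired analysis was possible because there is no other group of slides to pair with, and the pairing of both RNAs on a slide is already in its ratio. The number of slides limits what can be called, and spot signal over background is unknown. Ratios of small whole numbers, which low signals would give, made up 17.6%, 14.9% and 6.63% of values on slides 1, 2 and 3, against 2.61%, 2.23% and 3.11% by chance.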

Other observations

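The gene group described here was chosen after its values were seen, and so was its test.

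A set of 8 glp genes outside the fixed lists, for glycerol and glycerol-3-phosphate uptake and oxidation, was positive on all 3 slides, with a median of 1.41 (0.93 without slide 2). They were picked by hand. The glpX gene, of the same operon as glpF and glpK, had values on 2 slides and was not tested, and glpE, glpG and glpR, of another glp operon, were at -0.033 ± 0.53, -0.047 ± 0.43 and 0.37 ± 0.23 (SD, n = 3). The dehydrogenase genes glpA, glpB and glpC were at 1.47 ± 0.66, 1.36 ± 0.0084 and 1.60 ± 0.91 (SD, n = 3). The transporter and phosphodiesterase genes glpT and glpQ were at 1.49 ± 0.89 and 1.58 ± 1.29, the glycerol facilitator and kinase genes glpF and glpK at 1.10 ± 0.45 and 0.93 ± 0.27, and the aerobic dehydrogenase gene glpD at 0.69 ± 0.60. None of the 8 passed limma's test over all genes (adjusted p = 0.374 for each).

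The glp genes were noticed from glpA, glpB, glpF and glpK, which were among the first 40 genes by p. The other 4 (glpC, glpD, glpT and glpQ) had a median of 1.53, above 0.56, the upper bound of the middle 95% of random lists matched on the scatter of repeat spots. This comparison does not exclude that trend as the source, since the genes were picked after their values were seen and glpC shares an operon with glpA and glpB. Much of that median came from slide 2: without it the median was 0.93, against an upper bound of 0.61. As a hypothesis, these 8 glp genes may have been expressed more in MelR* cells. Genes of 1 operon are not independent, and a difference in culture conditions between the RNAs was not tested.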
